A study of Mus musculus with 36 samples.

How the data were processed

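Primary fibroblasts from the tendon, cornea and skin of CD1 mouse fetuses at day 19 after conception were grown for 5 population doublings and seeded on gelatin-coated glass. Per the labels' protocols, the cells were then kept for 14 h either under static medium or under laminar flow at a shear stress of 0.1 dyn/cm2. Total RNA was amplified and biotin-labelled from 100 ng per library, per the scan records of the arrays, and hybridised to both arrays (chips A and B) of the Affymetrix MOE430 set. A comment in a scan record says that the material of skin static 2 may have been more concentrated, and this library was kept. The 3 tissues and the static or flow state make 6 groups of 3 replicates, which gives 18 libraries and 36 arrays. A library is here the pair of chip A and chip B arrays that share a group and a replicate number in the labels. The series' design text calls the replicates biological, but no label says whether they came from separate fetuses or litters, so p-values measure the spread between these samples.

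The deposited values of each chip are on a log2 scale, and per the submitters' processing notes they come from RMA, which corrects background, normalises by quantiles and summarises the probes of a probe set. The version of RMA and the probe set definitions it used are not given in the sources used here. Each chip's table holds its 18 arrays together, and the chips were analysed as separately normalised tables. The number of arrays per group limits the precision of every value.

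Chip A holds 22690 probe sets and chip B 22575. After the 64 control probe sets of each chip were left out, 20380 probe sets of chip A and 14661 of chip B carried 1 gene symbol in the platform annotation. Another 691 and 245 carried several symbols, 1555 and 7605 carried none, and these were not used for gene results. Each gene was represented by 1 probe set. Chip A was taken before chip B, a probe set whose name marks cross-hybridisation was taken only if the gene had no other, and among the rest the probe set with the highest mean over the 18 arrays was taken. This gave 18193 genes, 12388 from chip A and 5805 from chip B. Of these genes 9040 had more than 1 probe set, and the other probe sets were examined for every named gene. The Entrez identifiers of 18032 representatives were found in the RefSeq gene table used here, and 0 symbols needed updating.

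Group means were fitted with limma 3.58.1 in R 4.3.3, separately for each chip, with all 6 groups in 1 model without covariates (residual degrees of freedom 12, prior degrees of freedom 4.05 for chip A and 4.29 for chip B). Moderated p-values of both chips were adjusted together over all 18193 genes by the Benjamini-Hochberg method, and a gene was called changed or different at an adjusted p below 0.05. The contrasts were flow against static in each tissue, the average of these 3 responses, the test of whether the 3 responses differ (interaction), the 3 pairwise differences between static tissues, and the joint test of tissue under flow. Errors given with log2 fold changes are standard errors of this fit, and errors given with group means are SDs of 3 libraries. The adjusted p-values below are from limma unless another test is named.

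Gene lists were tested with camera in limma at a preset correlation between genes of 0.01 over 39 lists, adjusted over the lists of a comparison, with at least 5 measured members required. The lists cover matrix, adhesion, mechanical, growth, metabolic, stress and immune genes, Hox genes, tissue identity genes and markers of other cell types that the cultures could hold. The test was repeated with the correlation estimated in each list, and the text gives that p-value for the lists called for flow in each tissue and on average and between static tissues. Fry, which asks whether the genes of a list move on balance in 1 direction, was run as an alternative. Counts adjusted over the list alone use the members of a list as the whole family of tests.

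The rule for named genes was fixed in advance. For flow it took the 12 largest positive and 12 largest negative changes among called genes whose 3 libraries of a state all lay beyond the 3 of the other state (for the average, among called genes with the same direction in 3 tissues), and up to 4 called genes per list. For static tissues it took the 10 largest each way and up to 4 called genes per identity list, Hox list and list of another cell type. The 15 smallest p-values were taken for the interaction. Where fewer than 5 genes were called, the 10 smallest p-values were listed and the genes that missed the threshold named as such. Clone and predicted gene names were counted but not named. Other list members given as examples were chosen after their values were seen.

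Scan records assigned 5 libraries to scan batch 1 (tendon static 1, tendon flow 1, skin static 1, skin flow 1 and cornea flow 1) and 13 to scan batch 2, and noted the culture day of the libraries in batch 2. Same-numbered static and flow libraries deviated together from their group means in tendon (r across genes 0.622, 0.382 and 0.425) and in skin (0.495, 0.763 and 0.57). In cornea they did not (-0.218, -0.433 and 0.408), where the noted days instead pair static 1 with flow 2 (0.673) and static 3 with flow 3 (0.408). A block for the culture day was therefore fitted as a fixed term for the flow comparisons, with the replicate 1 pair of scan batch 1 as 1 block in tendon and in skin (residual degrees of freedom 5). No day was noted for these replicate 1 pairs, which are counted among the culture-day pairs below. In cornea, static 2 and flow 1 had no partner in a block, so the blocked corneal response rests on the pairs named above. By the hybridisation times in the scan records, corneal static 1, 2 and 3 were all in run 2. Corneal flow 1, 2 and 3 were in runs 1, 3 and 2. Same-numbered tendon and skin libraries shared a run, and these tissues' static libraries were spread over runs 1 to 3. The run is thus mixed with flow in cornea and with tissue in the static corneal comparisons, and it was not fitted. The culture-day block was chosen after the scan records were read. As a random term it had a consensus correlation of 0.497 on chip A and 0.244 on chip B.

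The groups, the fits, the threshold, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined. Those alternatives were a block for the replicate number, a block for the scan batch, only the compared groups in the fit, dim genes left out, all probe sets, eBayes with trend and robust, arrayWeights, repeated quantile normalisation, cyclic loess, a minimum of 2-fold, adjustment within each chip, and each library left out in turn. Alternatives added after seeing the data were the culture-day blocks, scan batch 2 alone, the 3'-5' difference of beta-actin as a covariate, list tests with an estimated correlation without each library and with that covariate, the use of the lists between tissues, the sign-flip test of the 3' to 5' differences over culture-day pairs, and the splits that part these pairs.

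The fit was tested on simulated data with random seed 1, in which 1.5-fold, 2-fold and 4-fold changes were added to known genes among the 18193. For flow in tendon it recovered 49.3%, 80.6% and 98.5% of these, and for the average 82.1%, 98.5% and 100%, with 0 wrong signs. Among 17971 unchanged genes 5 were called for tendon and 10 for the average, and the 1 shifted list was found in each. The simulated noise was independent between genes and between libraries. The data hold correlations between genes and within culture days, so these counts do not measure false calls under such structure. Other splits of the libraries were counted over at most 100 splits. All arrays were used, and the intensities of single probes were not analysed here.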

Results

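Transcript levels of 18193 genes were measured in fibroblasts of fetal mouse tendon, cornea and skin, with 3 static and 3 flow libraries per tissue. Flow was a laminar shear stress of 0.1 dyn/cm2 for 14 h, which is low beside the stress on vessel walls. The comparisons ask what flow changed in each tissue, whether the tissues responded differently, and how the fibroblasts of the 3 tissues differed in static culture and under flow. Unless stated otherwise, values are log2 fold changes ± SE with 3 libraries per group. Libraries are named by tissue, state and replicate number.

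The fibroblasts of the cornea stood apart from those of tendon and skin. The leading principal component, with 24.4% of the variance, placed the corneal libraries between -28.47 and -16.16, the tendon libraries between 1.96 and 19.98 and the skin libraries between 4.61 and 17.25. On the next component (18%), tendon static 3 lay at -43.01, away from all other libraries (-15.94 to 21.93). Against the other tendon static libraries it was higher in the small nucleolar RNA host genes Snhg1 (2.01) and Snhg6 (1.91) and lower in the RNA helicase Ddx6 (-1.85). Its median difference was 0.3 for ribosomal proteins, -0.59 for TGF-beta targets, -0.51 for cholesterol synthesis and -0.37 for fibrillar collagens.

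**Figure D1:**
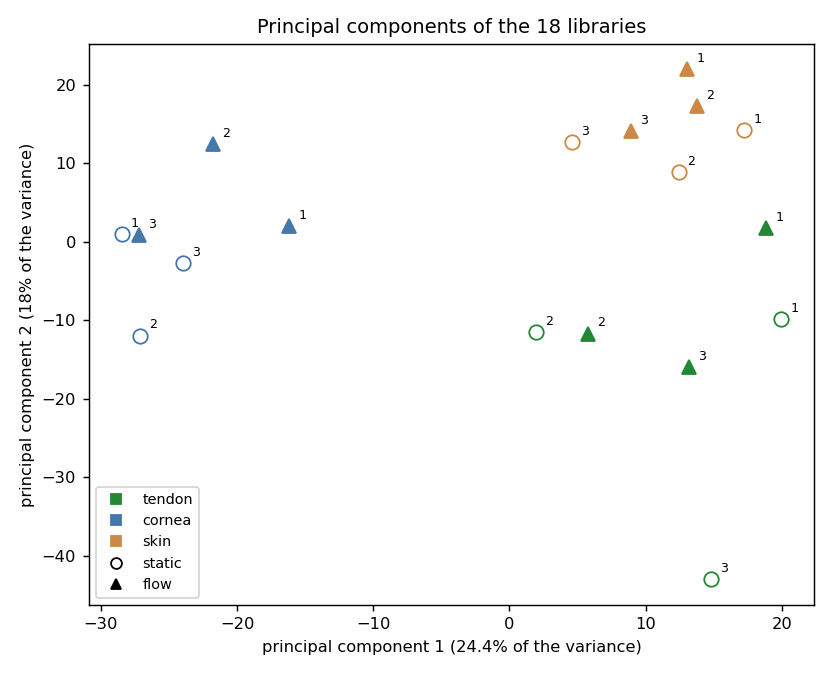
Scores of the 18 libraries on the leading 2 principal components, which hold 24.4% and 18% of the variance; open circles are static and triangles flow libraries, coloured by tissue, and the numbers are replicate numbers. The corneal libraries lie between -28.47 and -16.16 on the horizontal axis and tendon static 3 lies alone at -43.01 on the vertical axis.

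The 6 tendon flow arrays carry conflicting labels, since their description names cornea while their titles, sources and scan records name tendon. They were placed on a scale from 0 (static cornea) to 1 (static tendon) made of 219 genes. The tendon flow libraries lay at 1.009, 0.892 and 0.979 and the cornea flow libraries at 0.038, 0.1 and 0.013. They were analysed as tendon.

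The 3' to 5' difference of the control probe sets, a measure of RNA integrity and amplification length, lay higher under flow on chip B. Gapdh differed by 0.213 (exact permutation test within tissues, two-sided, p = 0.0468) and beta-actin by 0.282 (p = 0.0532). On chip A the differences were 0.099 for Gapdh (exact permutation p = 0.3012) and 0.213 for beta-actin (p = 0.1305). Within each tissue, 3 libraries against 3 allow no p under 0.1. That test does not use the culture-day pairs, which include the replicate 1 pairs of tendon and skin without a noted day. On chip B 7 of these 8 pairs were higher under flow for each control gene, all but that of tendon static 3. An exact sign-flip test over the pairs (two-sided) gave p = 0.0156 for Gapdh and 0.0703 for beta-actin on chip B (0.0624 and 0.125 adjusted over 4 tests). On chip A it gave 0.328 and 0.0938 (exact sign-flip test, 0.328 and 0.125 adjusted). Tendon static 3 had the highest beta-actin difference of the 9 static libraries on both chips, 1.391 against at most 1.095 and 1.492 against at most 1.08.

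In tendon fibroblasts, flow raised 10 genes and lowered 1 of 18193, and the largest rises were those of Srxn1, Gclm and Angptl4. Srxn1, which encodes the sulfiredoxin that repairs oxidised peroxiredoxins, went from 8.61 ± 0.14 to 10.72 ± 0.41 (mean ± SD, n = 3; 4.34-fold, limma adjusted p = 0.012). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose 4.23-fold (2.08 ± 0.30, adjusted p = 0.012). Gsta4, a glutathione transferase for products of lipid peroxidation, rose by 1.63 ± 0.21 (adjusted p = 0.0082). The chaperone genes Hsph1 (1.12 ± 0.15), Ahsa2 (0.83 ± 0.11) and Hspb1 (0.72 ± 0.12) rose as well. The others were Angptl4, a secreted inhibitor of lipoprotein lipase (1.96 ± 0.30), Procr, the protein C receptor (1.74 ± 0.28), the protease inhibitor Serpinb1b (1.66 ± 0.28) and the haem transporter Slc48a1 (1.15 ± 0.18). Lrrc17, a secreted leucine-rich repeat protein, fell by 1.43 (SE 0.21, adjusted p = 0.015). Other probe sets of Srxn1 gave 0.7, 0.96 and -0.02, another of Angptl4 gave 0.35 and another of Lrrc17 gave 0.08.

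Of 22 measured genes of the NRF2 antioxidant response, 3 rose in tendon (12 adjusted over the list alone), with a list median of 0.65 (adjusted p = 0.0041 with an estimated correlation). Of 14 heat shock genes 2 rose (5 adjusted over the list alone; median 0.44, adjusted p = 0.029 with an estimated correlation). The heat shock call ended without tendon static 1 (adjusted p = 0.25), flow 1 (0.052), flow 2 (0.083) or flow 3 (0.057), and the NRF2 call held in all 6 refits. Camera at the preset correlation also placed 7 lists lower, none of which held with an estimated correlation. These were cholesterol synthesis (median -0.47, adjusted p = 0.23 with an estimated correlation), cell cycle (-0.37, 0.49), inflammatory genes (-0.29, 0.26), small leucine-rich proteoglycans and hyaluronan (-0.20, 0.058), contractile and SRF targets (-0.10, 0.57), interferon response (-0.13, 0.26) and other genes named in advance (-0.25, 0.26). Without tendon static 3, cholesterol synthesis (median -0.58) and the proteoglycan list (-0.16) passed, each with an adjusted p of 0.034 with an estimated correlation. The 3 libraries of each state did not overlap for the 11 changed genes, while 8% of all genes showed no overlap against 10% by chance.

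The tendon calls rested on few libraries. Of 11 changed genes, 0 kept the call in all 6 refits, and the count was 0 without flow 1, 0 without flow 2, 2 without static 2 and 5 without static 3. In these refits Hsph1 and Ahsa2 lost the call without flow 1 or flow 2, Gsta4 in 3 and each of the others in 4 to 6. With the culture day as a block 220 genes changed (128 higher, 92 lower), the 11 among them, and this block cannot change the directions in tendon. The NRF2 list then had an adjusted p of 0.11 with an estimated correlation, and the heat shock list 0.11.

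In corneal fibroblasts, flow raised 3 genes and lowered 1. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose from 8.42 ± 0.06 to 9.76 ± 0.24 (SD, n = 3; 2.53-fold, limma adjusted p = 0.03). Abcb6, a porphyrin transporter, rose by 1.09 ± 0.14 (adjusted p = 0.011) and Cbr3, a carbonyl reductase, by 1.08 ± 0.16 (adjusted p = 0.03). The centromere gene Cenpp fell by 1.01 (SE 0.15, adjusted p = 0.03), with 0.03 and -0.85 for its other probe sets. Srxn1 (1.86, adjusted p = 0.055), Slc48a1 (1.07, 0.055), Gclm (1.72, 0.075), Gsta4 (1.21, 0.077), the inducible chaperone Hspa1a (1.64, 0.088) and Angptl4 (1.6, 0.12) did not pass the test. With the culture day as a block all but Angptl4 (0.07) passed, with adjusted p-values of 0.029, 0.0094, 0.035, 0.0094 and 0.03.

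In cornea 1 gene of the NRF2 list rose (12 adjusted over the list alone; median 0.52, adjusted p = 0.0046 with an estimated correlation). The heat shock list had 0 genes past the limma threshold (7 adjusted over the list alone) and a median of 0.39 (adjusted p = 0.028 with an estimated correlation). That of small leucine-rich proteoglycans and hyaluronan had a median of -0.19 (adjusted p = 0.038). Without static 1, static 3 or flow 2 the heat shock list had adjusted p-values of 0.065, 0.065 and 0.063, and the proteoglycan list had 0.13 without static 2, 0.096 without static 3, 0.26 without flow 1 and 0.084 without flow 2. Camera at the preset correlation also called 10 lists that an estimated correlation did not. They were hypoxia and glycolysis (median 0.14, adjusted p = 0.56 with an estimated correlation), cell cycle (-0.51, 0.40), cholesterol synthesis (-0.44, 0.32), fibrillar collagens (-0.13, 0.45), contractile genes (-0.15, 0.45), inflammatory genes (-0.25, 0.56), interferon response (-0.09, 0.50), Hox genes (-0.09, 0.45), dermal identity (-0.12, 0.32) and cartilage and bone (-0.13, 0.69).

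The corneal count of 4 genes became 0 without static 1, static 2, flow 1 or flow 2, and 11 without flow 3. It became 60 (51 higher, 9 lower) with the culture day as a block, the 4 among them. In that fit static 2 and flow 1 had no partner, so the response rested on static 1 with flow 2 and static 3 with flow 3. Static 1 and flow 2 were hybridised in different runs (2 and 3), so in this pair flow cannot be told apart from the run. With the replicate number as a block, or with the scan batch as one, 1 gene passed, and Gclc, Cbr3 and Cenpp lost the call. With the culture-day block the NRF2 list had an adjusted p of 0.12 with an estimated correlation, the heat shock list 0.12 and the proteoglycan list 0.46.

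In skin fibroblasts, flow raised 5 genes and lowered 0 (limma, 547 genes at an unadjusted p below 0.05 in either direction). Gclm rose from 9.76 ± 0.10 to 11.61 ± 0.33 (SD, n = 3; 3.59-fold, adjusted p = 0.047) and Gsta4 from 10.76 ± 0.16 to 12.26 ± 0.42 (2.82-fold, adjusted p = 0.018). Serpinb1b rose by 1.72 ± 0.28 (adjusted p = 0.047), Abcb6 by 0.98 ± 0.14 and Stxbp5, a syntaxin-binding protein of vesicle release, by 0.72 ± 0.10 (adjusted p = 0.018 for both; other probe sets of Stxbp5 0.2 and 0.58). Of the NRF2 list 2 genes rose (10 adjusted over the list alone; median 0.62, adjusted p = 0.0018 with an estimated correlation), and this call held in all 6 refits. The heat shock list had 0 genes past the threshold (4 adjusted over the list alone), with a median of 0.36 and an adjusted p of 0.052 with an estimated correlation.

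In skin camera at the preset correlation placed 9 lists lower, none with an estimated correlation. Their medians and adjusted p-values with an estimated correlation were -0.11 and 0.74 for fibrillar collagens, -0.15 and 0.11 for small leucine-rich proteoglycans, -0.16 and 0.40 for contractile genes, -0.31 and 0.74 for cell cycle, and -0.23 and 0.74 for cholesterol synthesis. They were -0.14 and 0.74 for inflammatory genes, -0.16 and 0.23 for interferon response, -0.09 and 0.74 for keratinocyte markers and -0.12 and 0.23 for smooth muscle and pericyte markers. The count of 5 genes became 0 without static 1, static 3 or flow 3, 1 without static 2 or flow 1 and 3 without flow 2. With the culture day as a block 66 genes changed (47 higher, 19 lower), the 5 among them, and the NRF2 list had an adjusted p of 0.13 with an estimated correlation.

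Averaged over the 3 tissues, flow changed 163 genes, 115 higher and 48 lower, and the largest rises among the named genes were those of Hmox1, Srxn1, Gclm and Angptl4. Hmox1, the haem oxygenase, rose 5.25-fold (2.39 ± 0.29, limma adjusted p = 0.00058). It went from 8.82 ± 0.47 to 11.15 ± 0.96 in tendon, from 9.41 ± 1.14 to 11.89 ± 0.11 in cornea and from 9.14 ± 0.32 to 11.5 ± 0.71 in skin (SD, n = 3). It differed by 2.72 in the tendon pair and 2.33 in the skin pair of scan batch 1 and by 2.33 in scan batch 2. Srxn1 rose 3.78-fold (1.92 ± 0.18, adjusted p = 3.6e-05), Gclm 3.68-fold (1.88 ± 0.17, adjusted p = 3.6e-05) and Gsta4 2.73-fold (1.45 ± 0.12, adjusted p = 2.5e-05). All 163 genes moved in the same direction in the 3 tissues, as did 47.2% of all genes. Calling genes on the average of the 3 responses favours such agreement, so it is not separate evidence of a shared response.

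Of the 22 genes of the NRF2 list 11 rose on average and 0 fell (15 higher and 1 lower adjusted over the list alone). The median was 0.59 (adjusted p = 0.0017 with an estimated correlation), and the call held without each of the 18 libraries but not with the culture day as a block (adjusted p = 0.097 with an estimated correlation). With that block, which leaves 5 residual degrees of freedom, 0 of the 39 lists passed with an estimated correlation in any flow comparison. Besides Hmox1, Srxn1, Gclm and Gsta4, the genes that rose included Gclc (1.19 ± 0.12), the quinone reductase Nqo1 (1.12 ± 0.17, adjusted p = 0.0029), the thioredoxin reductase Txnrd1 (1.01, 0.018) and catalase, Cat (0.81, 0.029). The cystine transporter Slc7a11 (1.03, adjusted p = 0.051) and the glutathione reductase Gsr (0.67, 0.072) did not pass. The list median was 0.58 in the tendon pair and 0.67 in the skin pair of scan batch 1, 0.53 in scan batch 2 and 0.57 with the scan batch as a block. Chip B's 3' to 5' differences lay higher with flow too (Gapdh 0.213). With the beta-actin difference, averaged over both chips of a library, as a covariate the list median was 0.55 (adjusted p = 0.012 with an estimated correlation). The Gapdh difference was not used as a covariate.

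Genes outside that list that rose on average were Angptl4 (1.78 ± 0.17, 3.44-fold), Serpinb1b (1.59 ± 0.16), Procr (1.51 ± 0.16), the biliverdin reductase Blvrb (1.44 ± 0.18), the iron exporter Slc40a1 (1.27 ± 0.21) and Pgd, an enzyme of the pentose phosphate pathway (1.24 ± 0.16). Gsta2, another glutathione transferase, rose by 1.29 ± 0.25 (adjusted p = 0.022) and lost the call without skin static 1, static 3 or flow 3. Genes that fell included the chemokines Cxcl5 (-1.14 ± 0.23) and Ccl20 (-0.86 ± 0.15), the pentraxin Ptx3 (-0.90 ± 0.16), Lrrc17 (-0.86 ± 0.12) and Lrch2 (-0.86 ± 0.13), besides Tk1 and Ube2c, given below with the cell cycle. The follistatin gene Fst (-0.75 ± 0.15, adjusted p = 0.026), Gbp2 (-0.74 ± 0.17, 0.047) and the fatty acid binding protein Fabp5 (-0.72 ± 0.16, 0.049) also fell. Other probe sets gave 0.59, 1.08 and -0.04 for Srxn1 and 0.01 for Lrrc17. They gave 0.2 for Angptl4, 0.21 for Slc40a1 and -0.09 for Ptx3, far less than the values above.

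**Figure D2:**
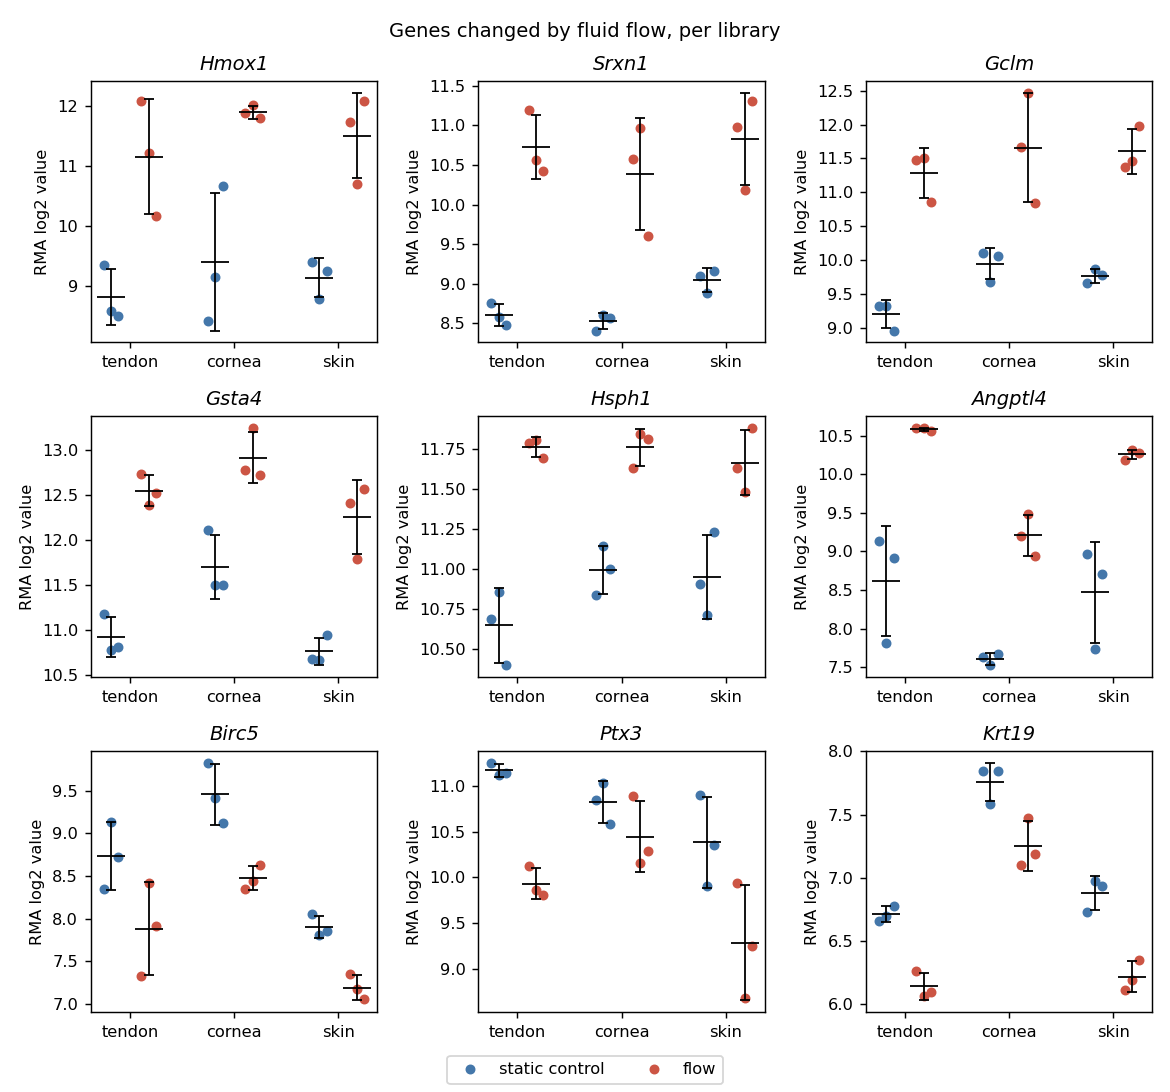
Log2 expression of Hmox1, Srxn1, Gclm, Gsta4, Hsph1, Angptl4, Birc5, Ptx3 and Krt19 in each library, static and flow side by side for each tissue; bars are means and error bars SDs of 3 libraries. On average flow raised Hmox1 by 2.39 and Hsph1 by 0.87 and changed Ptx3 by -0.90 and Birc5 by -0.85.

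Of 14 heat shock genes 5 rose on average (8 adjusted over the list alone; median 0.43, adjusted p = 0.013 with an estimated correlation), a call that held without each library. They were Hsph1 (0.87 ± 0.09, adjusted p = 5.7e-05), Hspa1a (1.03 ± 0.17, 0.007), Hspa4l (0.79 ± 0.12, 0.0029; other probe sets 0 to 0.71), the small heat shock protein Hspb1 (0.48 ± 0.07, 0.0015) and the crystallin chaperone Cryab (0.62 ± 0.12, 0.016). The median was 0.65 in the tendon pair and 0.45 in the skin pair of scan batch 1 and 0.42 in scan batch 2. With the 3' to 5' difference of beta-actin, which lay higher with flow, as a covariate it was 0.46 (adjusted p = 0.015 with an estimated correlation). Of 16 genes of small leucine-rich proteoglycans and hyaluronan 1 fell, the large proteoglycan Vcan (-0.56 ± 0.11, adjusted p = 0.02; other probe sets -0.27 to 0.06), with 2 lower adjusted over the list alone. That list had a median of -0.15 (adjusted p = 0.014 with an estimated correlation), and -0.21, -0.19 and -0.08 in the tendon pair, the skin pair and scan batch 2. With the covariate its median was -0.17, and it did not pass with an estimated correlation (adjusted p = 0.11). Its osteoglycin Ogn (-0.87, adjusted p = 0.39) and lumican Lum (-0.64, 0.32) did not pass. With the culture day as a block they did, with adjusted p-values of 0.00052 and 0.002, but each of these 3 lists then had an adjusted p of 0.097 with an estimated correlation.

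Genes of cell division and cholesterol synthesis lay lower under flow, without passing as lists once the correlation was estimated. Of 31 cell cycle genes 1 fell, the survivin gene Birc5 (-0.85 ± 0.14, adjusted p = 0.0066), and 6 were lower adjusted over the list alone. The median was -0.37 (adjusted p = 0.3 with an estimated correlation), and -0.32, -0.24 and -0.35 in the tendon pair, the skin pair and scan batch 2. It was -0.33 with the 3' to 5' difference of beta-actin, which itself lay higher with flow, as a covariate. Outside the list Ube2c (-0.90 ± 0.17), Tk1 (-0.91 ± 0.21) and Cdca3 (-0.77 ± 0.14; other probe sets -0.12 and -0.12), genes expressed in dividing cells, fell. Cyclins Ccna2 (-0.81, adjusted p = 0.16) and Ccne2 (-1.09, 0.14) did not pass but did with the culture day as a block (0.00072 and 0.0014), where 16 of the 31 were lower. Of 17 cholesterol synthesis genes 1 fell, the mevalonate kinase Mvk (-0.43 ± 0.09, adjusted p = 0.043; another probe set -0.17), with 10 lower adjusted over the list alone and 8 with the block. The median was -0.38 (adjusted p = 0.18 with an estimated correlation), and -0.4, -0.18 and -0.36 in the tendon pair, the skin pair and scan batch 2.

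Camera at the preset correlation called 6 further lists on average, all lower and none with an estimated correlation. Of 28 inflammatory genes 2 fell (3 adjusted over the list alone; median -0.25, adjusted p = 0.28 with an estimated correlation), and of 21 interferon response genes 1 (2 adjusted over the list alone; median -0.14, 0.18). No gene passed limma's threshold among 26 contractile genes (median -0.11, adjusted p = 0.28), 30 growth factors (-0.11, 0.2), 18 cartilage and bone genes (-0.08, 0.67) and 12 other genes named in advance (-0.16, 0.31). With the 3' to 5' covariate the contractile list (camera adjusted p = 0.11), growth factors (0.059) and the other genes named in advance (0.13) were not called at the preset correlation either. The covariate also brought preset calls of hypoxia and glycolysis (median 0.14, camera adjusted p = 0.01), the unfolded protein response (0.10, 0.039), corneal identity (-0.16, 0.0088) and the keratinocyte (-0.13, 0.0088), endothelial (-0.12, 0.04), macrophage (-0.12, 0.013) and melanocyte and glial (-0.15, 0.0075) markers. None of these 7 held with an estimated correlation (adjusted p from 0.31 to 0.6).

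**Figure D3:**
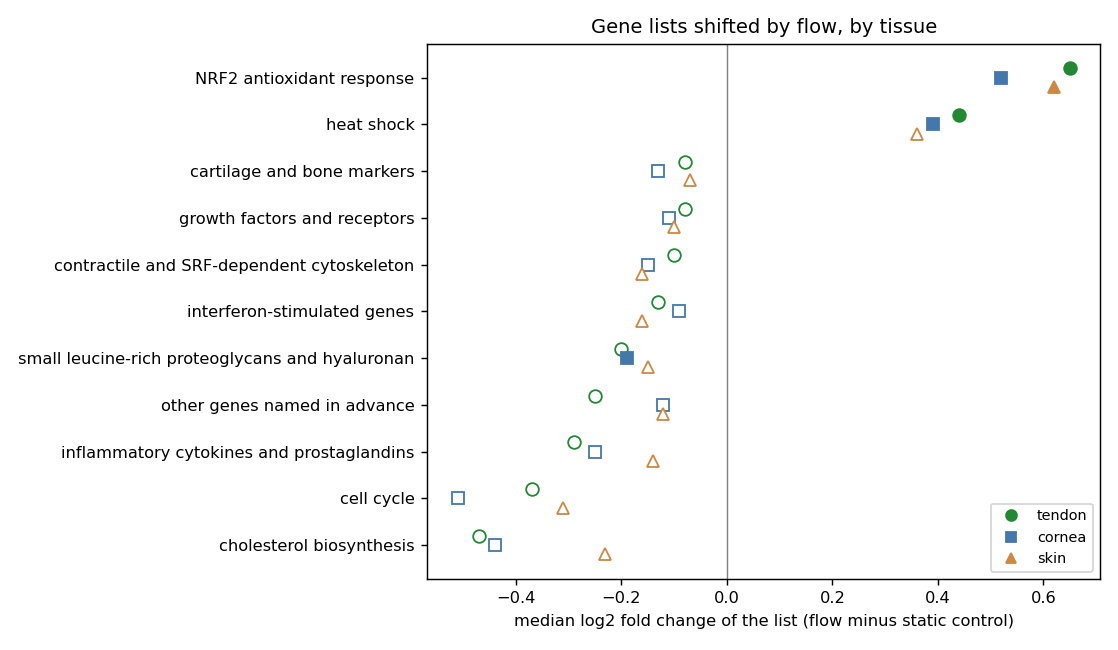
Median log2 change under flow of the 11 gene lists called on average at the preset correlation, for tendon, cornea and skin; filled points passed with an estimated correlation in that tissue and open points did not. The NRF2 list has medians of 0.65, 0.52 and 0.62, and the cell cycle list -0.37, -0.51 and -0.31, without passing in any tissue.

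The other 28 lists were not called on average, and the medians below stand with camera's adjusted p. Among matrix and adhesion lists they were fibrillar collagens (-0.09, adjusted p = 0.051), basement membrane (0.02, 0.69), collagen processing (0.02, 0.91), matrix proteases (-0.01, 0.37) and integrins (-0.04, 0.25). The lists of mechanical and growth signals were immediate early genes (-0.16, 0.26), YAP and TAZ targets (-0.03, 0.91), TGF-beta targets (-0.02, 0.54), BMP and Id genes (-0.08, 0.084), Wnt (-0.05, 0.26) and mechanosensitive channels and gap junctions (-0.01, 0.91). Hypoxia and glycolysis (0.10, 0.051), oxidative phosphorylation (-0.02, 0.68), the unfolded protein response (-0.03, 0.83), complement (-0.14, 0.17) and ribosomal proteins (-0.03, 0.78) were not called either. The identity lists were Hox genes (-0.04, 0.25), tendon (-0.08, 0.4), cornea (-0.10, 0.051) and dermis (-0.07, 0.42). Markers of other cell types were keratinocyte (-0.06, 0.061), endothelial (-0.09, 0.093), skeletal muscle (-0.02, 0.78), macrophage (-0.08, 0.16), adipocyte (-0.05, 0.67), melanocyte and glial (-0.08, 0.26), smooth muscle and pericyte (-0.14, 0.051) and lens and retina (-0.05, 0.25). Single genes of these lists that changed were Fst (-0.75), Bmp6 (0.34 ± 0.08), the aldehyde dehydrogenase Aldh3a1 (0.58 ± 0.11) and the keratin Krt19 (-0.58 ± 0.07). The mechanically induced genes Egr1 (-0.62, adjusted p = 0.59), Fos (-0.47, 0.75), Ccn1 (-0.04, 0.95) and Ccn2 (-0.14, 0.55) did not pass, nor did Col1a1 (-0.03, 0.91).

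The average count fell to 101 without skin static 1, 106 without skin flow 1, 98 without skin flow 3 and 103 without tendon flow 1. Of 33 named genes 24 kept the call in every refit. Besides Gsta2, those that did not were Cxcl5 (lost without 7 libraries), Tk1 (14), Fst (10), Gbp2 (15), Fabp5 (16), Bmp6 (16), Mvk (15) and Aldh3a1 (without skin flow 1). With the 3' to 5' difference of beta-actin as a covariate Gsta2, Cxcl5, Tk1, Fst, Gbp2, Fabp5 and Mvk lost the call, and of the 178 genes that passed 115 were among the 163. In scan batch 2 alone 32 genes passed on average, 30 of them among the 163, and 0 in each single tissue. Among the named genes that did not pass there were Blvrb, Slc40a1, Pgd, Birc5, Vcan, Hspa1a and Ccl20. With the culture day as a block 1273 genes changed (853 higher, 420 lower), the 163 among them in the same direction.

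No difference between the tissues in their response to flow passed the test. Limma's interaction test called 0 of 18193 genes, with 142 at an unadjusted p below 0.05. The smallest p-values belonged to Pcp4l1 (-0.67 in tendon, 0.06 in cornea, -0.09 in skin), Acap2 (0.15, -0.36, 0.29), Cenpp (-0.71, -1.01, -0.11), Myct1 (-0.07, -0.61, -0.02) and Ahsa2 (0.83, 0.25, 0.45), each with an adjusted p of 1. So the genes called in 1 tissue alone were not shown to differ from the other tissues. Of the 10 genes that rose in tendon and the 5 that rose in skin, 3 were shared, where 0.0027 would be by chance (Fisher's exact test, p = 1.195e-09). Cornea and skin shared 1 (Fisher's exact p = 8.243e-04) and tendon and cornea 0, and 38, 29 and 30 were shared in these pairs of tissues with the culture day as a block. Fisher's test takes genes as independent, and the tissues share each gene's estimate of spread, so its p-values can overstate the agreement. Across genes, which are not independent, the responses correlated with r = 0.628 (rho 0.493) for tendon and skin, 0.562 (0.443) for tendon and cornea, and 0.556 (0.44) for cornea and skin. Without tendon flow 1, tendon and cornea gave r = 0.349.

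In static culture 240 genes differed between tendon and skin, 106 higher and 134 lower in tendon, and 140 of them by at least 2-fold. Tendon was higher in Ppbp, a platelet chemokine (10.96 ± 0.28 against 7.18 ± 0.23, SD, n = 3; 13.7-fold, adjusted p = 1.7e-05), and in Prg4, the lubricin of gliding surfaces (3.59 ± 0.34, 12.1-fold). It was also higher in the thrombospondin Thbs4 (3.08 ± 0.29), the cochlin gene Coch (2.9 ± 0.19), the Wnt modulator Sfrp2 (2.81 ± 0.17), Hoxb13 (2.67 ± 0.22) and Igfbp4 (2.42 ± 0.24). Skin was higher in Hoxc8 (-4.14 ± 0.18, 17.7-fold, adjusted p = 2.5e-09), the protease inhibitor genes Ctla2a (-3.05 ± 0.17) and Ctla2b (-2.35 ± 0.13), the scavenger receptor Olr1 (-2.71 ± 0.24) and the apolipoprotein Apod (-2.67 ± 0.32). The limb homeobox gene Lhx9 (-2.42 ± 0.25), Plac8 (-2.11 ± 0.29) and the transglutaminase Tgm2 (-2.09 ± 0.13) were likewise higher in skin.

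Of 30 Hox genes 3 were higher and 5 lower in tendon than in skin (3 and 9 adjusted over the list alone), and the list was called lower at the preset correlation but not with an estimated correlation (median -0.10, adjusted p = 0.49). The 3 higher in tendon were Hoxa11 (1.71 ± 0.16), Hoxa10 (1.45 ± 0.14; another probe set 0.12) and Hoxc13 (1.32 ± 0.17). Hoxb13, given above as higher in tendon, is not a member of this list, so neither the counts nor the list test include it. Of 16 tendon identity genes 3 were higher (4 adjusted over the list alone; median 0.14, adjusted p = 0.094 with an estimated correlation), Thbs4, the fibromodulin Fmod (0.9 ± 0.17) and the transcription factor Mkx (0.91 ± 0.21). Of 19 dermal identity genes 1 was higher and 4 lower (3 and 6 adjusted over the list alone, 1 and 2 without tendon static 3; median -0.14, 0.11). These included the dermatopontin Dpt (-2.24 ± 0.45), Tbx15 (-0.85 ± 0.15), Dlk1 (-1.92 ± 0.37), Lrig1 (-0.79 ± 0.11; other probe sets 0.08 and -1.17) and Trps1 (0.97 ± 0.2; other probe sets 1.15, 0.94 and -0.12). Among markers of other cell types Mcam (-1.93 ± 0.29), Flt1 (-1.06 ± 0.24) and the muscle genes Acta1 (-1.35 ± 0.26) and Tnnt2 (-1.64 ± 0.37; other probe sets 0.08 and -1.55) were lower in tendon.

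The lists of the basement membrane and integrins were shifted lower in tendon than in skin. Of 14 basement membrane genes 4 were lower (7 adjusted over the list alone; median -0.58, adjusted p = 0.0085 with an estimated correlation), the laminins Lama2 (-0.81 ± 0.19) and Lamb1 (-0.74 ± 0.15), the agrin Agrn (-0.66 ± 0.16) and Col4a1 (-0.5 ± 0.11). Without tendon static 3, 0 of the 14 passed, while the list still did (median -0.51, adjusted p = 0.011 with an estimated correlation). Of 22 integrin genes 1 was lower, Itga8 (-0.95 ± 0.22), and the list had a median of -0.24 (adjusted p = 0.012 with an estimated correlation, 0.086 without skin static 3 and 0.061 without tendon static 3). At the preset correlation camera called 14 lists between tendon and skin, 4 higher and 10 lower in tendon, and these 2 held with an estimated correlation. Besides the Hox and identity lists above, those that did not hold were fibrillar collagens (median -0.29, adjusted p = 0.094 with an estimated correlation), matrix proteases (-0.38, 0.22), contractile genes (-0.27, 0.21), YAP and TAZ targets (-0.34, 0.18) and TGF-beta targets (-0.32, 0.47). Cell cycle (0.46, 0.54), cholesterol synthesis (-0.28, 0.54), oxidative phosphorylation (0.11, 0.46) and cartilage and bone (0.11, 0.76) did not hold either. Without tendon static 3 the medians were -0.20 for fibrillar collagens, -0.21 for proteases, -0.12 for YAP and TAZ targets, -0.16 for TGF-beta targets, -0.15 for cholesterol synthesis and 0.05 for cartilage and bone. The last 3 were then not called at the preset correlation (camera adjusted p = 0.23, 0.15 and 0.12). The count of 240 genes fell to 140 without skin static 1, 126 without skin static 3 and 159 without tendon static 3, and was 86 in scan batch 2, where Fmod, Tbx15 and Mcam lost the call besides Smoc2, Mkx, Dlk1, Trps1, Flt1, Acta1 and Tnnt2. Of 33 named genes 25 kept the call in each refit. Mkx, Flt1 and Tnnt2 lost it in 5 of 6, Dpt in 4, Smoc2 (2.39 ± 0.48) and Dlk1 in 3, and Trps1 and Acta1 in 2.

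Between cornea and skin 449 genes differed in static culture, 247 higher and 202 lower in cornea. The water channel genes Aqp1 (10.17 ± 0.48 against 5.97 ± 0.31, SD, n = 3; 18.5-fold, adjusted p = 1.8e-08) and Aqp5 (3.12 ± 0.37) were higher in cornea. So were the retinaldehyde dehydrogenase Aldh1a1, an abundant protein of the cornea in several mammals (3.45 ± 0.28, 11-fold), Igfbp2 (3.32 ± 0.62), the scavenger receptor Scara3 (3.11 ± 0.19), the natriuretic peptide receptor Npr3 (2.89 ± 0.33) and the craniofacial homeobox gene Alx1 (2.82 ± 0.23). Skin was higher in Hoxc8 (-4.92 ± 0.18, 30.3-fold), Dpt (-4.12 ± 0.45, 17.4-fold), C1qtnf3 (-4.11 ± 0.33), Ctla2a (-3.34 ± 0.17), Olr1 (-3.01 ± 0.24) and the peptide hormone gene Cck (-2.97 ± 0.12).

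Of 30 Hox genes 14 were lower in cornea and 0 higher (16 lower adjusted over the list alone; median -0.49, adjusted p = 0.003 with an estimated correlation), and the call held in all 6 refits. They included Hoxc10 (-2.71 ± 0.3), Hoxd8 (-1.88 ± 0.17) and Hoxb2 (-1.4 ± 0.15). Of 21 corneal identity genes 4 were higher (9 adjusted over the list alone; median 0.14, adjusted p = 0.096 with an estimated correlation), Aldh1a1 and the transcription factors Tfap2b (2.29 ± 0.15), Foxc1 (1.89 ± 0.16) and Foxc2 (1.14 ± 0.25), which take part in the development of the anterior eye. Of the dermal list 1 gene was higher and 7 lower (4 and 8 adjusted over the list alone; median -0.17, 0.2), with Twist2 (-2.14 ± 0.18) and Dlk1 (-2.14 ± 0.37) among the lower. Of 31 cell cycle genes 8 were higher in cornea (21 adjusted over the list alone; median 1.01, adjusted p = 0.2 with an estimated correlation), for example the proliferation marker Mki67 (2.16 ± 0.48), the checkpoint kinase Bub1 (2.04 ± 0.4), Cenpa (1.9 ± 0.32) and Birc5 (1.55 ± 0.24). The keratin Krt19 was higher (0.88 ± 0.12) and the lipoprotein lipase Lpl lower (-2.1 ± 0.36).

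Camera at the preset correlation called 8 lists between cornea and skin, 3 higher and 5 lower in cornea, of which the Hox list alone held with an estimated correlation. The others not given above were fibrillar collagens (median -0.38, adjusted p = 0.2 with an estimated correlation), matrix proteases (-0.61, 0.2), oxidative phosphorylation (0.13, 0.51) and interferon response (-0.20, 0.43). The count of 449 genes fell to 255 without cornea static 2, 231 without skin static 1 and 298 without skin static 3, and was 174 in scan batch 2, where Tfpi2, Igfbp3, Six2, Fmod, Foxc2, Dlk1, Lrig1 and Acta1 lost the call. Of 34 named genes 31 kept the call in each refit. Igfbp3 (-2.79 ± 0.63) and Acta1 (-1.08 ± 0.26) lost it in 5 of 6 and Foxc2 in 4.

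**Figure D4:**
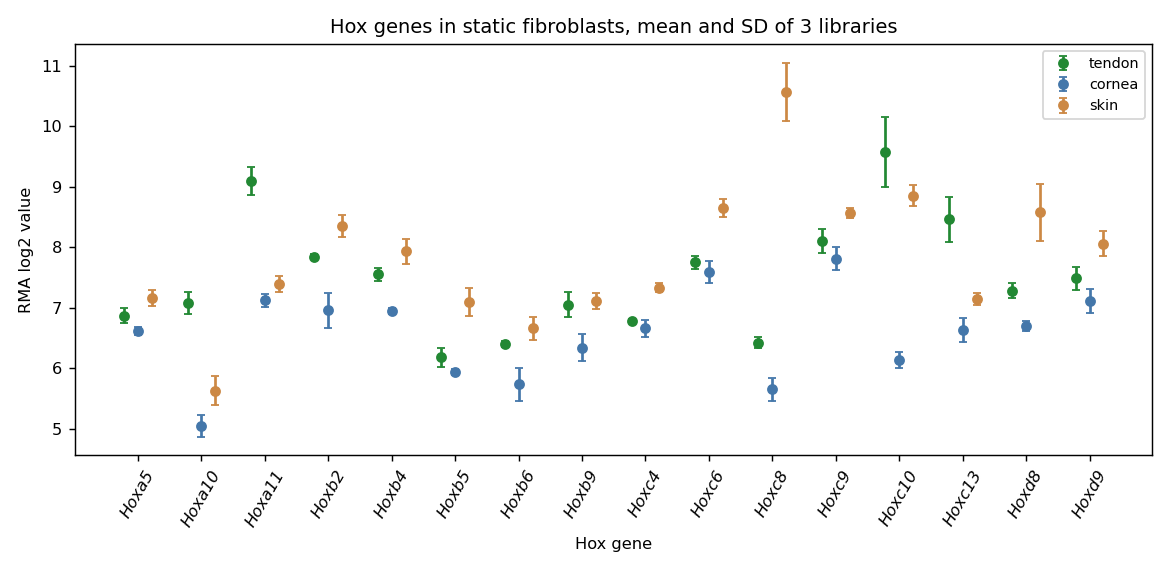
Mean log2 expression of 16 Hox genes in static tendon, cornea and skin fibroblasts; error bars are SDs of 3 libraries. Hoxc8 stands at 10.57 in skin against 6.42 in tendon and 5.65 in cornea.

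Between tendon and cornea 444 genes differed in static culture, 198 higher and 246 lower in tendon. Tendon was higher in the secreted protein C1qtnf3 (4.06 ± 0.33, 16.6-fold, adjusted p = 1.9e-06), the matricellular Smoc2 (4.01 ± 0.48, 16.1-fold), Cck (3.4 ± 0.12, adjusted p = 6.5e-11), Prg4 (3.32 ± 0.34) and Wnt4 (2.93 ± 0.25). Cornea was higher in Aldh1a1 (-4.56 ± 0.28, 23.6-fold), Igfbp2 (-4.5 ± 0.62, 22.6-fold), Npr3 (-3.68 ± 0.33), Aqp1 (-3.44 ± 0.23), Aqp5 (-3.18 ± 0.37), the osteoprotegerin gene Tnfrsf11b (-3.06 ± 0.36), Alx1 (-2.93 ± 0.23) and the heparan sulfatase Sulf1 (-2.83 ± 0.21; other probe sets 0.11 and -2.93).

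Of 30 Hox genes 8 were higher in tendon than in cornea and 0 lower (13 higher adjusted over the list alone; median 0.28, adjusted p = 0.013 with an estimated correlation), led by Hoxc10 (3.44 ± 0.3), Hoxa10 (2.03 ± 0.14), Hoxa11 (1.98 ± 0.16) and Hoxc13 (1.83 ± 0.17). Of 21 corneal identity genes 6 were lower (1 higher and 10 lower adjusted over the list alone; median -0.29, adjusted p = 0.092 with an estimated correlation), with Tfap2b (-2.27 ± 0.15), Foxc1 (-1.73 ± 0.16) and Col8a1, a collagen of Descemet's membrane (-1.68 ± 0.29). Of 16 tendon identity genes 2 were higher, Thbs4 (2.66 ± 0.29) and Cilp (1.23 ± 0.29), and Six2 was lower (-0.68 ± 0.16). The list, with 4 higher and 2 lower adjusted over the list alone, was not shifted (median 0.15, camera adjusted p = 0.19). Of 14 basement membrane genes 2 were lower in tendon (2 adjusted over the list alone), Nid2 (-1.56 ± 0.12) and Lama2 (-1.51 ± 0.19), with a median of -0.36 (adjusted p = 0.029 with an estimated correlation, 0.05 without cornea static 1 and 0.086 without tendon static 2). Of 22 integrin genes 1 was higher and 1 lower (1 and 3 adjusted over the list alone; median -0.27, 0.013). The keratin Krt19 (-1.05 ± 0.12) and Perp (-1.87 ± 0.33), an epithelial adhesion gene, were higher in cornea.

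Camera at the preset correlation called 9 lists between tendon and cornea, 1 higher and 8 lower in tendon, of which the Hox, basement membrane and integrin lists held with an estimated correlation. Besides the corneal list, those that did not were contractile genes (median -0.19, adjusted p = 0.4 with an estimated correlation), YAP and TAZ targets (-0.31, 0.12), cell cycle (-0.59, 0.57), the unfolded protein response (-0.20, 0.64) and heat shock (-0.17, 0.64). Without tendon static 3 the basement membrane median was -0.12 (adjusted p = 0.049 with an estimated correlation), heat shock was not called at the preset correlation (camera adjusted p = 0.095), and the corneal list passed with an estimated correlation (0.04). The count of 444 genes lay between 311 and 647 in the 6 refits and was 211 in scan batch 2, where Ccl8, Six2, Cilp, Crabp1, Tbx18, Dpt, Perp, Lpl and Mcam lost the call. Of 38 named genes 33 kept the call in each refit. Cilp lost it in 5 of 6, and Six2, Tbx18 (-0.8 ± 0.18), Dpt (1.89 ± 0.45) and Lpl (1.58 ± 0.36) in 4.

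Under flow 513 genes differed between the 3 tissues, and genes that led the static differences were among them. Hoxc8 stood at 10.46 ± 0.17 in skin, 6.4 ± 0.05 in tendon and 5.33 ± 0.17 in cornea (SD, n = 3; adjusted p = 1.4e-10). Aldh1a1 stood at 10.49 ± 0.45 in cornea, 6.98 ± 0.65 in skin and 6.05 ± 0.26 in tendon (adjusted p = 1.5e-07), and Prg4 at 10.99 ± 0.21 in tendon, 7.42 ± 0.45 in skin and 7.01 ± 0.52 in cornea (2.2e-06). Of the 668 genes that differed between static tissues 413 also differed under flow, where 18.8 would by chance, although static and flow libraries share culture days and so are not independent. Of these 413 genes 382 had the same sign between tendon and skin and 400 between cornea and skin. Hox genes were lower in cornea than in skin (14 of 30; median -0.48, adjusted p = 0.00055 with an estimated correlation) and higher in tendon than in cornea (9 of 30; median 0.34, 0.0042). The tendon identity list passed between tendon and skin (3 of 16 higher; median 0.12, adjusted p = 0.035 with an estimated correlation), and the corneal list between cornea and skin (5 of 21 higher; median 0.09, 0.049) and between tendon and cornea (5 of 21 lower in tendon; median -0.38, 0.042). The dermal list was lower than in skin both in tendon (4 of 19; median -0.06, adjusted p = 0.035 with an estimated correlation) and in cornea (6 of 19; median -0.18, 0.012). The integrin list was shifted lower in tendon than in skin (median -0.24, adjusted p = 0.016 with an estimated correlation) with 0 of 22 genes passing, and than in cornea (-0.21, 0.042) with 0 lower and 1 higher. The basement membrane list was shifted lower in tendon than in skin (1 of 14 lower; median -0.35, 0.026), while against cornea (-0.22, 0.1) that list did not pass. Trps1 (adjusted p = 0.10), Cilp (0.075) and Tbx18 (0.053), which differed between static tissues, did not pass under flow. In scan batch 2 alone 179 genes passed.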

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

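The list tests of differences between responses, and the tests of the scan batch, the culture day, the tissue label and the RNA integrity of tendon static 3, and the splits that part the 8 culture-day pairs, were chosen only after the result was seen. At the preset correlation camera found 6 lists whose flow response differed between tissues, none of them with an estimated correlation. Between tendon and skin the medians of the difference were 0.13 for fibrillar collagens, 0.13 for basement membrane, 0.26 for YAP and TAZ targets, -0.23 for cholesterol synthesis and -0.09 for oxidative phosphorylation (adjusted p = 0.89 each with an estimated correlation). Between cornea and skin the cell cycle list differed by -0.29 (adjusted p = 0.98 with an estimated correlation). Between tendon and cornea 0 lists were called. With the culture-day block the preset correlation called 9 lists between tendon and skin, 9 between cornea and skin and 7 between tendon and cornea. With an estimated correlation 0 of these passed. Of 10096 probe sets without a single gene name, which no comparison above uses, 13 changed under flow on average, 11 higher and 2 lower.

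The list of NRF2 antioxidant genes lay higher under flow with a median of 0.59, although not all of its genes passed. The values argue against the scan batch, and against RNA integrity as measured by beta-actin, as the whole cause. The median was 0.53 in scan batch 2 alone (0.44 to 0.65 without each of its libraries) and 0.55 with the beta-actin covariate (0.45 to 0.64). The hybridisation run, which is mixed with flow in cornea, was not tested. With the culture-day block the median was 0.54 (0.47 to 0.69). In tendon and skin each block holds as many static as flow libraries, so only the corneal part of the average could move. The culture-day block therefore does not test the day in tendon and skin. With that block the list did not pass with an estimated correlation (adjusted p = 0.097 on average and 0.11 to 0.13 in the tissues), although its median stayed. An effect of flow on the NRF2 response, or of medium handling that goes with flow, stays open as a hypothesis and was not tested.

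The cell cycle genes lay lower under flow, with a median of -0.37 that did not pass with an estimated correlation. The scan batch (-0.35 in scan batch 2 alone, -0.46 to -0.21 without each of its libraries) is argued against as the whole cause. With the culture-day block the median was -0.37 (-0.48 to -0.25). That block could move only the corneal part of the average, so it does not test the day in tendon and skin. RNA integrity stays open, since with the 3' to 5' covariate the median was -0.33 and came to -0.18 in a refit without 1 library, beyond the bound set for this test. Slower division under flow may be a biological source of the pattern, which these data cannot separate from RNA integrity.

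Tendon static 3 lay apart from the other tendon libraries. Of its 4 differences between 3' and 5' control probe sets, 0 lay outside the range of the other 17 libraries but 2 outside that of the other 8 static libraries, and its interquartile range was the lowest on both chips (2.667 and 2.054), so RNA integrity stays open. It stood at 0.951 on the scale from cornea to tendon and 0.983 on that from skin to tendon, which argues against a wrong tissue label. The highest median among markers of other cell types was 0.22 (macrophage), below what a large share of such cells would bring. Other biological explanations were not tested, as the labels put it in the same group as the others.

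Other splits of the libraries into groups of the same sizes gave these counts. For the average response 2 of 100 splits, the real one included, gave as many genes (real 163, highest other 238). That share lies under 0.05, but most of these splits keep some culture-day pairs together, so they do not exclude chance. The split with 238 genes parted 2 of the 6 culture-day pairs of tendon and skin, counting the replicate 1 pairs without a noted day. It put 4 of the 5 libraries of scan batch 1 on 1 side. Since 2 other splits that parted 2 pairs gave 2 and 1 genes, and another with 4 of these 5 libraries on 1 side gave 4, the structure behind the 238 stays open. Among the 18 others of these 100 that part all 6 pairs the highest was 0, and these are too few for a share under 0.05. In 100 of the 256 splits that part all 8 pairs of the culture-day block, the real one included, no other count was as large (highest other 6). For tissues under flow the real split alone of 100 gave as many genes (real 513, highest other 151), a share under 0.05 that does not exclude chance. For the interaction the real count of 0 makes all 100 splits as large (highest other 16), so the splits say nothing. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 11 and 1 for flow in tendon, 5 and 0 in skin, 240 and 0 for tendon and skin, 449 and 0 for cornea and skin, and 444 and 3 for tendon and cornea. In cornea they were 4 and 49, and the split with 49 keeps both noted culture-day pairs together, where the blocked count is 60.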

How the results depend on the processing

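The culture-day blocks, scan batch 2 alone, the 3' to 5' covariate and the list tests without each library were chosen after seeing the data; the other alternatives were planned. Counts of called genes are given where they moved by more than 1.5 times, and no called gene changed sign under another block, normalisation, weighting, filter, variance model or covariate or in scan batch 2. For part of these a change was not possible. The blocks are balanced against flow in tendon and skin and cannot change the fold changes there, and filters and variance models leave all fold changes as they are. Where a count moved or a call was lost, the cause was not tested. For flow in tendon (11 genes) the count was 21 with the scan batch as a block, 19 over all probe sets, 33 with arrayWeights, 220 with the culture-day block, 111 with it as a random block, 18 with the 3' to 5' covariate, 6 with only the compared groups and 0 in scan batch 2, where fewer libraries are left. For flow in cornea (4) it was 1 with the replicate block, 1 with the scan batch block, 9 without dim genes, 9 over all probe sets, 8 with trend and robust, 19 with arrayWeights, 10 after repeated quantile normalisation, 9 after cyclic loess, 60 and 38 with the fixed and random culture-day block, 9 with the covariate, 0 in scan batch 2 and 0 with only the compared groups. For flow in skin (5) it was 3 with the scan batch block, 24 with arrayWeights, 8 adjusted within each chip, 66 and 42 with the fixed and random culture-day block, 0 in scan batch 2, 0 with only the compared groups and 3 at 2-fold or more. For the average (163) it was 426 with arrayWeights, 1273 and 1166 with the fixed and random culture-day block, 32 in scan batch 2 and 20 at 2-fold or more. The interaction count was 0 under every alternative run, the refits without each library included.

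Between static tendon and skin (240) the count was 86 in scan batch 2, 124 with only the compared groups and 140 at 2-fold or more. Between cornea and skin (449) it was 697 over all probe sets, 794 with arrayWeights, 174 in scan batch 2 and 246 at 2-fold or more. Between tendon and cornea (444) it was 800 over all probe sets, 211 in scan batch 2, 194 with only the compared groups and 219 at 2-fold or more. Under flow (513) it was 803 over all probe sets, 1110 with arrayWeights, 179 in scan batch 2 and 316 at 2-fold or more. With the replicate number as a block, the counts were 14 in tendon (11 shared), 6 in skin (5 shared), 200 on average (157 shared) and 302, 579 and 547 between static tissues, and apart from flow in cornea this block moved none of these counts by over 1.5 times.

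Without each library in turn the counts ranged from 0 to 8 in tendon, 0 to 11 in cornea, 0 to 3 in skin, 98 to 178 on average, 126 to 242 between tendon and skin and 231 to 418 between cornea and skin. With tendon static 3 left out the average count was 124 and the tendon and cornea count 316. Of the lists, 2 held with an estimated correlation in tendon, 3 in cornea, 1 in skin and 3 on average, and fry called 2, 3, 1 and 7. With the culture-day block camera called 18 lists on average. Without each library camera called 7 to 13 lists in cornea, 7 to 13 in skin and 8 to 18 on average. The correlation across genes between tendon and cornea responses was 0.483 with the culture-day block, 0.458 in scan batch 2 and 0.349 to 0.61 without each library. That of tendon and skin was 0.671 without dim genes, 0.52 in scan batch 2 and 0.522 to 0.613 without each library, and that of cornea and skin 0.427 to 0.586 without each library.

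Other probe sets reversed the direction of some named genes. They gave -0.02 in tendon, -0.11 in cornea and -0.04 on average for Srxn1, 0.08 in tendon and 0.01 on average for Lrrc17, 0.03 in cornea for Cenpp and 0.06 and 0.04 on average for Vcan, whose other 5 lay between -0.27 and 0. Between static tissues they gave 0.08 for Lrig1, -0.12 for Trps1 and 0.08 for Tnnt2 (tendon and skin) and 0.11 for Sulf1 (tendon and cornea). With the sign kept, they were far weaker between tendon and skin for Igfbp4 (0.29), Apod (-0.03), Lhx9 (-0.43 and -0.49), Tgm2 (-0.29 and -0.1), Hoxa10 (0.12), Tbx15 (-0.19) and Dlk1 (-0.24), between cornea and skin for Npr3 (0.81 and 0.36) and Dlk1 (-0.25), and between tendon and cornea for Tnfrsf11b (-0.52) and Hoxa10 (0.01). Those of Alx1 were far smaller too (0.46 between cornea and skin, -0.48 between tendon and cornea) but still passed. So did the smaller values of Wnt4 (0.84) and Npr3 (-1.07 and -0.55) between tendon and cornea. Among the genes named on average, Gbp2 lost the call after cyclic loess and after repeated quantile normalisation, and Bmp6 after cyclic loess. In scan batch 2 alone 12 of the 33 genes named on average passed, among them Hmox1, Srxn1, Gclm, Gsta4, Hsph1, Ptx3 and Krt19. In tendon cyclic loess ended the calls of Procr and Hspb1 and quantile normalisation that of Procr. In skin the scan batch block and quantile normalisation ended those of Gclm and Serpinb1b, and cyclic loess and the covariate that of Gclm. Between tendon and skin cyclic loess ended those of Mkx, Trps1 and Tnnt2, and between tendon and cornea both normalisations ended that of Six2. Signal over background was not analysed here, and the number of arrays limits the precision.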

Other observations

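The tests of the pentose phosphate, haem and PPAR lists and the genes named in this and the next paragraph were chosen only after the result was seen. Of 25 fibrillar collagen and matrix genes, 3 were lower in tendon than in skin (5 adjusted over the list alone; median -0.29, adjusted p = 0.094 with an estimated correlation), Col12a1 (-1.19 ± 0.2), Fbn2 (-1.1) and the fibronectin gene Fn1 (-0.65). Without tendon static 3, 1 was lower and the median was -0.20. Between cornea and skin 1 was lower, the thrombospondin Thbs2 (-1.65). Of 21 matrix protease genes 3 were lower in tendon than in skin, Mmp9 (-1.34), Timp3 (-1.28) and Adamts1 (-1.23), with a median of -0.38 (adjusted p = 0.22 with an estimated correlation; 2 lower and -0.21 without tendon static 3). In cornea against skin Mmp10 (-2.48), Adamts4 (-0.71) and the cathepsin Ctsk (-1.45) were lower and Mmp16 higher (1.68), with a median of -0.61 (adjusted p = 0.2 with an estimated correlation).

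Single genes of signalling were called between static tissues, although the Wnt, BMP, TGF-beta and growth factor lists did not pass with an estimated correlation. Tendon was higher than skin in Bmp4 (1.18) and the gap junction gene Gja1 (1.68) and lower in Wnt5a (-1.26), Fst (-1.86) and the phosphatase Dusp4 (-1.76). Cornea was higher than skin in the Wnt inhibitor Dkk2 (1.95) and lower in Wnt4 (-2.73) and the TGF-beta induced matrix gene Tgfbi (-2.3). The YAP targets Ankrd1 (-2.09 ± 0.36) and Crim1 (-2.17 ± 0.35) were lower in tendon than in cornea, and their list had a median of -0.31 (adjusted p = 0.12 with an estimated correlation).

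If the NRF2 genes were part of a wider programme under flow, proteasome, pentose phosphate and haem genes may rise with them. Of 31 proteasome genes 26 had positive changes on average, with a median of 0.11 (adjusted p = 0.24 with an estimated correlation). The pentose phosphate and NADPH list had a median of 0.09 (0.24) and the haem list 0.09 (0.053). These p-values on average miss the threshold and so neither bear out nor exclude the hypothesis, although the bound written for them would have read them as excluding it. In skin alone the haem list passed (median 0.14, adjusted p = 0.042 with an estimated correlation), but not in tendon (0.22) or cornea (0.23). The tested haem genes include Slc40a1 (1.27 on average, 1.34 in skin), named above among the genes that rose. The haem p-values are therefore not independent of the results that led to the list.

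Further lists addressed other hypotheses on the average response to flow. Shared SREBP regulation may lower fatty acid synthesis genes with those of cholesterol synthesis, but their list stood at a median of -0.09 (adjusted p = 0.43 with an estimated correlation), which decides nothing. Of 23 lysosome and autophagy genes 21 had positive changes, with a median of 0.15 (adjusted p = 0.19 with an estimated correlation), which leaves a lysosomal programme open. The bounds written in advance for the fatty acid and lysosome lists would have read these p-values as excluding the hypotheses. A p-value that misses the threshold cannot exclude them. Of 13 PPAR targets 2 rose, the carnitine palmitoyltransferase Cpt1a (0.61 ± 0.11) and the acyl-CoA dehydrogenase Acadl (0.69 ± 0.11), and the list had a median of 0.07 (adjusted p = 0.049 with an estimated correlation). The PPAR list passed in tendon (adjusted p = 0.029 with an estimated correlation) and skin (0.042) but not in cornea (0.23). Another 3 members, whose values had been seen, were left out of it. The p-values of these further lists were adjusted among the further lists alone. The PPAR call was not tested without each library, with the 3' to 5' covariate or with the culture-day block. PPAR activity is a candidate explanation of the small shift of this list, found on the same data.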
